A study of Rattus norvegicus with 16 samples.

How the data were processed

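Gene expression was measured in 16 RNA samples from cultures of rat olfactory mucosa, the tissue of the nasal cavity that holds the olfactory epithelium and the connective tissue beneath it. Per the labels, the cells came from male Fischer rats and were sorted by flow cytometry into 4 populations with 4 biological replicates each. The populations were named CD90, p75, TRKA and TRKA-TGF. CD90 is the surface glycoprotein encoded by Thy1 and p75 the low-affinity neurotrophin receptor encoded by Ngfr. The TRKA-TGF cells were TRKA cells from cultures conditioned with transforming growth factor alpha, and the other 3 populations shared a culture protocol. Purity after sorting was 93 to 97%, per the labels. Groups and replicate numbers were taken from the sample titles. The labels do not say whether equal replicate numbers mark the same animals or cultures.

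RNA was isolated on magnetic beads from lysed cells, amplified as cDNA by a global PCR protocol and hybridised with Cy3 on single-colour Agilent rat arrays, per the labels' protocols. PCR amplification of small amounts of RNA can widen differences between samples, above all for scarce transcripts. The deposited scanner files hold spot intensities on a linear scale, per the file headers. The Feature Extraction version is 10.7.3.1 in the headers and 10.5 in the submitters' processing notes. The processed signal used here is a background-subtracted intensity, per the file headers. Each array had 58717 spots that were not controls and 4259 control spots, and no spot was saturated. Slides and scans were told apart by their header entries. All p75 and TRKA arrays lay on slide 1 and all TRKA-TGF and CD90 arrays on slide 2, each slide with its own scan. TRKA versus p75 and TRKA-TGF versus CD90 were therefore compared within a slide, and in the other 4 comparisons slide and group cannot be told apart. On slide 1 the p75 arrays lay in row 1 and the TRKA arrays in row 2, and on slide 2 the TRKA-TGF arrays in row 1 and the CD90 arrays in row 2. Within a slide, group and row therefore cannot be told apart either.

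The authors also deposited a table of log2 values for the same arrays. Its scale and centring are not given in the sources used here. Set against the scanner files, each column ran on a line of slope 1.00 (r = 0.999999 across probes) with quantile-normalized log2 processed signals centred on each probe's median over the 16 arrays. The column medians ranged from −0.03 (CD90 replicate 1) to 0.19 (TRKA replicate 2). That table was used as an alternative only.

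Values here were log2 of the processed signal minus the 75th percentile of the same array over all probes that were not controls. A level of 0 thus means the 75th percentile of the array. Spots that the scanner software marked as non-uniform or as population outliers were left out, and spots of one probe were averaged, which gave 30367 probes. Probes were named through the RefSeq accession of their target in a gene table of the GRCr8 assembly (18355 probes) or through a symbol or synonym (3180 probes), and 8832 probes kept the name in the scanner files. Positions are those of the array files, on rn4 (RGSCv3.4), and no position was taken from the newer assembly. A probe was kept when it was well above background on at least 4 of the 16 arrays, whatever their group. A gene was represented by its kept probe with the highest mean over all arrays, which left 20572 genes, 14109 with a current symbol and 6463 without.

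Differences were tested with limma 3.58.1 in R 4.3.3 (tables handled with the package data.table, version 1.17.8). A model with 1 mean per group was fitted to all 16 arrays, so that the groups shared one estimate of spread, followed by empirical Bayes moderation without a trend. Adjusted p is the Benjamini-Hochberg value over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are those of the fit. The 6 comparisons of the 4 populations were made. As a single measure of TRKA-TGF against TRKA, the genes called in CD90 versus p75 were signed toward p75 and averaged on each array. Exact permutation tests were two-sided over the 70 assignments of 8 arrays into groups of 4. A gene not well above background on any array of a group has only a bound there. Its difference is given as at least N-fold, computed from the mean of the brighter group and, in the dimmer group, from the mean over arrays of the higher of the lowest signal among probes well above background and the probe's own signal. Such a bound is approximate and no guaranteed minimum, since a probe with a signal above that lowest one can still be marked as not well above background.

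Before the data were examined, 20 gene lists were fixed from general knowledge, with 415 genes, 407 of them on the array. The marker lists were olfactory ensheathing and Schwann glia, myelin, fibroblast and mesenchymal, smooth muscle and myofibroblast, epithelial, olfactory epithelium neurons and sustentacular cells, neuronal, macrophage and myeloid, lymphocyte and mast cell, and endothelial. The pathway lists were cell cycle, matrix proteases and inhibitors, neurotrophic and growth factors, EGF receptor and MAPK response, axon guidance and adhesion, cytokines and chemokines, interferon response, stress and immediate early, stem and progenitor, and fatty acid and cholesterol synthesis. Some genes stand in more than 1 list, such as Egr1 (stress and MAPK response). Lists were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 20 lists of a comparison, and again with an estimated correlation. Counts of members are given over all genes tested and adjusted over the list alone.

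The rule for naming genes was also fixed before the data were examined. It takes genes behind the sort, Thy1 and Ngfr among them, together with Tgfa and Egfr. In each of 4 comparisons it then takes the 10 genes higher and the 10 lower with the largest differences among called genes whose arrays did not overlap between groups, that were well above background on all 4 arrays of the brighter group and that have a proper symbol, and 3 each way in TRKA-TGF versus p75 and TRKA-TGF versus CD90. Non-overlap of 4 and 4 arrays has a chance of 0.0286 for a single unchanged gene. It also takes the called list members with the largest differences as examples. Symbols of the Mup, Obp, RT1, Olr and Vom families are uncertain because of near-identical copies. List members that explain a small count were in some places named after their values were seen, and these are named as such. A few genes that the rule takes are not reported here, although they stayed in the fits and the lists.

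The gene and list tests were checked on simulated arrays with the means of the real genes, 200 changed genes and 1 shifted list. With each group's own spread, 28% of genes changed by 2 on the log2 scale and 92% of those changed by 8 were called in CD90 versus p75, and 43 of 20350 unchanged genes were called, among 135 calls in all. In TRKA-TGF versus TRKA these were 46%, 94% and 174 of 20350, among 297 calls in all. With one pooled spread, 26% and 82% were called in CD90 versus p75 with 8 false calls, and 24% and 86% in TRKA-TGF versus TRKA with 3 false calls. False calls were thus more frequent with unequal spreads in both comparisons. The shifted list was called in each of the 4 simulations, and of the other lists 0 were called by camera. Genes were drawn independently of each other there, so this does not show how often camera calls unchanged lists whose genes vary together. The number of arrays limits the precision of every value.

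Alternatives were quantile normalization, normexp background correction (offset 50), no filter, a filter at 8 arrays, the mean of a gene's probes, a fit of the 2 compared groups alone, trended and robust moderation, array weights, replicate number as a block, the authors' values, a 2-fold minimum, spots with outlier marks kept, camera with an estimated correlation, fry, and leaving out each array. After the data were seen, a fit without the TRKA arrays and a fit over the genes well above background on all 16 arrays were added. A fit with slide as a block was not run, since each group lies on 1 slide.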

Results

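Expression of 20572 genes was compared between CD90, p75, TRKA and TRKA-TGF cells sorted from rat olfactory mucosa cultures, with 4 biological replicates per population on one array each. Values are log2 signal relative to the 75th percentile of the array, and differences are the first population named minus the second.

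The p75 cells expressed a glial set of genes and the CD90 cells a fibroblast and smooth muscle set, whereas both TRKA populations expressed a myeloid set at high levels. Fewer transcripts were measurable in TRKA cells than elsewhere. On the TRKA arrays 54.5 ± 2.60% of spots were well above background (mean ± SD, n = 4), against 70.02 ± 1.31% for p75, 71.3 ± 0.801% for CD90 and 68.4 ± 2.08% for TRKA-TGF. Median processed signals were 31.8 ± 7.34 in TRKA, 202 ± 16.6 in p75, 174.0 ± 8.77 in CD90 and 154 ± 17.6 in TRKA-TGF. Replicates correlated at r = 0.736 to 0.761 in TRKA, 0.843 to 0.893 in p75, 0.835 to 0.848 in CD90 and 0.894 to 0.908 in TRKA-TGF. The median SD per gene was 1.08 in TRKA and 0.54 to 0.68 in the other groups, so levels of weakly expressed genes in TRKA are uncertain.

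**Figure D1:**
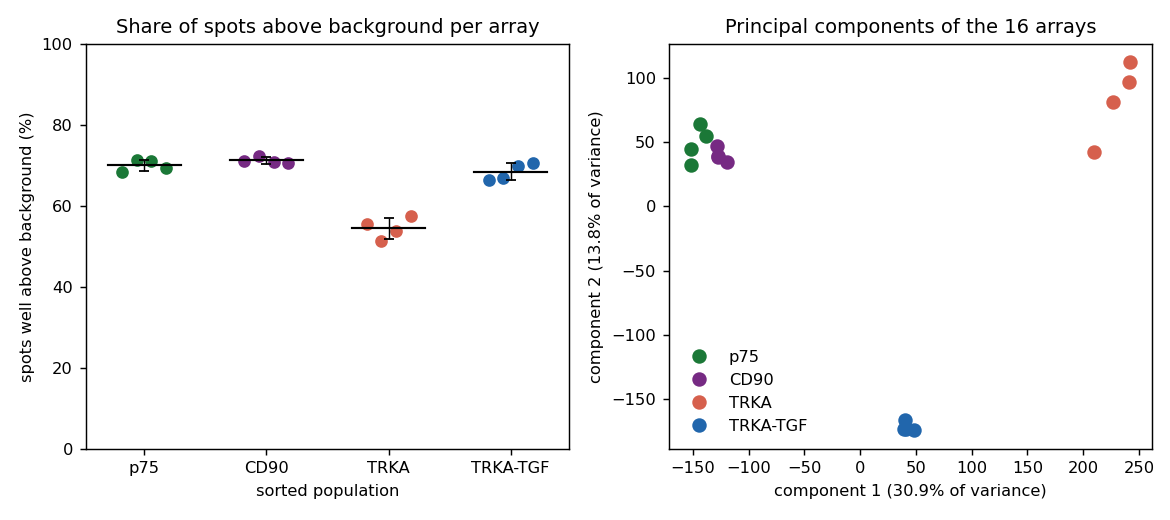
Percent of spots well above background on each array by population (points, with bars for mean ± SD; TRKA 54.5 ± 2.60%), and principal components of the log2 levels of all 16 arrays (component 1, 30.9% of variance; component 2, 13.8%). Each point is 1 array, coloured by population.

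Transcripts of the CD90 and p75 surface proteins followed the sort. Thy1, which encodes CD90 (Entrez 24832, chromosome 8, 47031186 to 47031646), stood at 3.44 ± 0.29 in CD90 cells and −1.56 ± 0.32 in p75 cells, and was well above background on 2 of 4 TRKA arrays and 1 of 4 TRKA-TGF arrays. Ngfr (24596, chromosome 10, 84263082 to 84263141) stood at 3.16 ± 0.24 in p75 cells, was well above background on 2 CD90 arrays and on 0 TRKA arrays, and stood at −0.37 ± 0.73 in TRKA-TGF cells. These 2 genes restate the sort where p75 or CD90 cells are compared.

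Tgfa (24827, chromosome 4, 120432206 to 120432265), the gene of the factor added to the medium, had 2 probes that disagreed. The brighter one gave no call in any comparison, and the other was called lower than in p75 in CD90 (−3.85, adjusted p = 0.0116), TRKA (adjusted p = 0.000618) and TRKA-TGF (adjusted p = 0.0013; limma over probes, Benjamini-Hochberg). That probe was well above background on 4 p75, 2 CD90, 0 TRKA and 0 TRKA-TGF arrays. Egfr, its receptor, was well above background on all 4 CD90 arrays (0.78 ± 0.56), on 1 array each of p75 and TRKA and on 2 of TRKA-TGF, and was not called (CD90 versus p75, adjusted p = 0.0864).

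**Figure D2:**
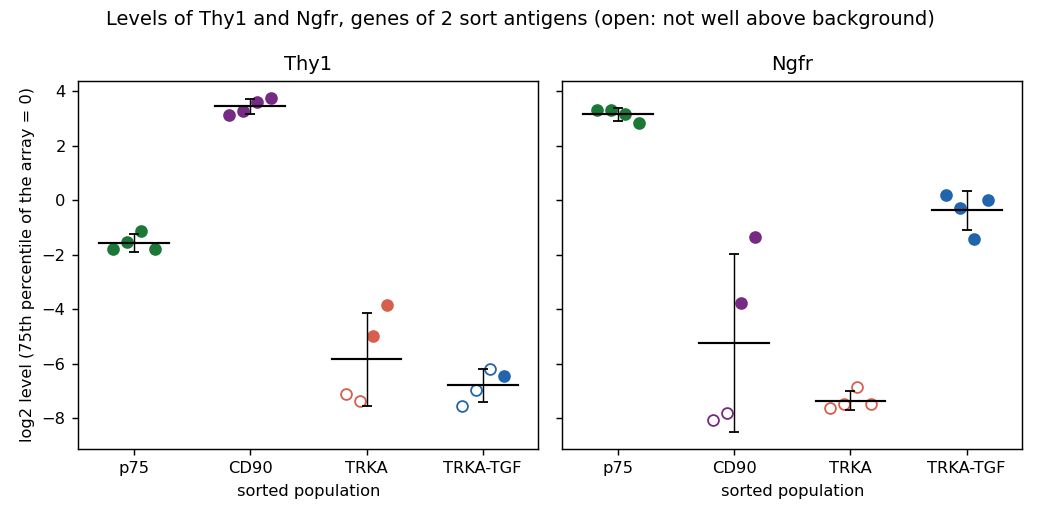
Log2 level relative to the 75th percentile of the array for Thy1 and Ngfr on each array by population (points; open where not well above background; lines and error bars, mean ± SD). Thy1 stood at 3.44 ± 0.29 in CD90 and Ngfr at 3.16 ± 0.24 in p75.

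CD90 cells had 758 genes higher and 733 lower than p75 cells, with 18 of 23 glia genes lower and 7 of 23 fibroblast genes higher. Aoc3, an amine oxidase of vessels and fat cells (29473, chromosome 10, 90364882 to 90364941), was at least 1177-fold higher in CD90, Omd at least 491-fold, Fmo1 at least 402-fold and the fatty acid carrier Fabp4 at least 343-fold. None of these 4 was well above background on any p75 array. The small proteoglycans Epyc (9.10) and Aspn (8.82), the signalling genes Bmp4 (9.23), Penk (9.39) and Epha7 (9.52) and the protocadherin Pcdh19 (8.89) were also higher, and were measured on 1 p75 array each (Aspn on 2). The largest adjusted p of these 10 genes was 0.000526 (limma, Benjamini-Hochberg).

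Among the genes lower in CD90 was Scn7a, a sodium channel gene of non-myelinating glia (64155, chromosome 3, 48634739 to 48634798), at least 5702-fold lower. The neuregulin receptor Erbb3 was at least 787-fold lower, Plxnb3 at least 802-fold, the retinoid enzyme Aldh1a1 at least 785-fold, Pla2g5 at least 559-fold, Tmem117 at least 542-fold and Ajap1 at least 396-fold. Fabp7 (−10.19), Dclk2 (−9.93) and the retinoid receptor Rxrg (−9.90) were lower as well, each measured on 1 CD90 array. All 10 had an adjusted p of at most 0.000342 in limma with Benjamini-Hochberg adjustment.

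Among the glia genes, 18 of 23 were lower and 1 (Alcam, 1.58) was higher in CD90, with a median of −5.74 and 4 not called; adjusted over the list alone the counts were the same. Sox10, the regulator of neural crest glia, was lower by −9.33 and L1cam by −7.37. Myelin genes were lower in 6 of 13, and in 7 adjusted over the list alone, with 7 not called and a median of −1.87. Ugt8, an enzyme gene of myelin lipid synthesis, was at least 82.2-fold lower. Both lists were called by camera with Benjamini-Hochberg adjustment (glia, adjusted p = 4.97e-27; myelin, 2.08e-06), and both calls held with an estimated correlation (7.97e-07 and 0.00288).

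Fibroblast genes were higher in CD90 in 7 of 23 and lower in 1 (Fbln2, −2.24), with 15 not called, and 12 were higher adjusted over the list alone (median 2.85). Col6a1 (8.02), Col6a2 (6.98) and Mfap5 (at least 131-fold) were among the higher ones. Smooth muscle genes were higher in 5 of 12 (10 adjusted over the list alone; 7 not called; median 2.92), among them Lmod1 (7.14), Mylk (6.44), Cnn1 (4.40) and Rgs5 (at least 74.6-fold). Macrophage genes were also higher in CD90, in 10 of 22 (11 adjusted over the list alone; 12 not called; median 1.79), including Mrc1 (4.18). All 3 lists were called by camera with Benjamini-Hochberg adjustment (adjusted p = 2.08e-06, 6.80e-10 and 1.91e-07) and with an estimated correlation (0.0157, 0.00017 and 0.0038).

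Stress and immediate early genes were lower in 5 of 21 and higher in 1 (Hmox1, 1.05), with 15 not called and a median of −0.66 (2 higher and 6 lower adjusted over the list alone). Atf3 (−6.40), Gadd45a (−2.73) and Fos (−1.96) were lower. The camera test with Benjamini-Hochberg adjustment gave adjusted p = 0.0206, and adjusted p = 0.237 with an estimated correlation. Cell cycle genes had a median of 1.33, with Mki67 (1.78) alone called over all genes, 22 not called and 3 higher adjusted over the list alone (camera, adjusted p = 0.0126; 0.047 with an estimated correlation).

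Axon guidance and adhesion genes went both ways, with 9 higher, 5 lower and 12 not called of 26 (11 higher and 6 lower adjusted over the list alone). The repellents Sema3d (7.59) and Sema3a (7.81) and the receptor Robo1 (7.07) were higher in CD90, and the glial adhesion gene L1cam (−7.37) was lower. Matrix proteases and inhibitors were called in 1 gene higher (Timp2, 2.11) and 3 lower, Adamts4 (−6.06), Plat (−2.91) and Serpine2 (−2.31). Growth factors were called in 3 higher and 2 lower of 22, with Hgf (4.26) higher. Cytokines gave 2 higher, with Il18 (2.06), and 1 lower of 19, stem and progenitor genes 3 lower of 15 with Itga6 (−8.53) and Sox2 (−3.52), fatty acid and cholesterol genes 1 higher of 19 (Srebf1, 3.89), and MAPK response genes 1 lower of 24 (Spry2, −2.02). No interferon gene was called over all genes, with 2 higher and 1 lower of 17 adjusted over the list alone. Adjusted over the list alone the counts were 3 higher and 4 lower for proteases, 7 and 6 for growth factors, 5 and 1 for cytokines and 0 and 4 for stem genes. These 8 lists were not called by camera with Benjamini-Hochberg adjustment (adjusted p = 0.201 axon guidance, 0.455 proteases, 0.7504 growth factors, 0.319 cytokines, 0.680 stem, 0.7504 fatty acid, 0.816 MAPK and interferon). Median and mean differed in sign for MAPK (0.11 and −0.16), interferon (0.04 and −0.32) and stem genes (0.31 and −0.53).

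In CD90 versus p75, limma with Benjamini-Hochberg adjustment called 1491 genes, 7.25% of those tested. The populations lay on different slides and scans, so slide and group cannot be told apart.

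TRKA cells, compared with p75 cells on the same slide, had lower levels of 20 of 23 glia genes and higher levels of all 22 macrophage genes. Snx20, a leukocyte sorting nexin (307742, chromosome 19, 19726030 to 19726089), was higher in TRKA by 11.55, the scavenger receptor of macrophages Cd163 (312701, chromosome 4, 160423704 to 160423763) by 10.68, and Mnda by 10.52. The leukocyte signalling genes Fyb1 (at least 1101-fold), Vav1 (at least 909-fold), Cd83 (at least 943-fold) and Itgb2 (at least 859-fold) were not well above background on any p75 array, nor was Rarres1 (at least 942-fold). Lcp1 (10.45) and Nt5dc2 (10.03) were measured on 1 and 2 p75 arrays. Snx20, Cd163 and Mnda were also measured on some p75 arrays only, so these differences rest partly on levels not above background. All 10 had an adjusted p of at most 2.93e-05 in limma with Benjamini-Hochberg adjustment.

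The protease gene Plat (25692, chromosome 16, 73711476 to 73711535), at 4.94 ± 0.05 in p75, was at least 3161-fold lower in TRKA. The glial genes Scn7a (at least 3175-fold), Lgi4 (at least 2837-fold), S100b (at least 1496-fold) and Ncam1 (at least 1447-fold) were lower, as were Hmgn3 (at least 3298-fold), the basement membrane gene Nid1 (at least 2763-fold), Rarres2 (at least 2477-fold) and the prion protein gene Prnp (at least 1499.7-fold). Lrrc61 fell by 11.49 and was measured on 1 TRKA array. None of the other 9 was well above background on any TRKA array, and the largest adjusted p of the 10 was 2.20e-06 (limma, Benjamini-Hochberg).

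All 22 macrophage genes were higher in TRKA than in p75, with a median of 6.66, among them Tyrobp (8.77) and the endotoxin co-receptor gene Cd14 (8.46). Glia genes were lower in 20 of 23 and higher in 1 (Alcam, 3.21), with 2 not called and a median of −7.02, and myelin genes were lower in 7 of 13 and higher in 1 (Egr2, 4.98), with a median of −1.91. Cnp (−7.35) and Mog (at least 74.3-fold) were among the lower ones. For these 3 lists the counts adjusted over the list alone were the same. Camera with Benjamini-Hochberg adjustment called the 3 lists (macrophage, adjusted p = 2.70e-18; glia, 2.15e-13; myelin, 0.000851), also with an estimated correlation (9.39e-05, 4.30e-05 and 0.0166).

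Axon guidance genes were lower in 11 of 26 with 15 not called (median −1.003), fatty acid and cholesterol synthesis genes in 11 of 19 with 8 not called (median −2.52), and fibroblast genes in 7 of 23 with 16 not called (median −2.99). Adjusted over the list alone, 11, 11 and 6 were lower. Sema3b (−8.86), L1cam (−8.72) and Sema3c (−8.05) stood for the first, the desaturases Fads1 (−8.95) and Fads2 (−8.02) for the second, and Postn (−10.65), Loxl1 (at least 450-fold) and Tnc (−8.55) for the last. The camera test with Benjamini-Hochberg adjustment called all 3 (adjusted p = 0.000495, 0.000851 and 0.00193), and the fibroblast call was lost with an estimated correlation (adjusted p = 0.104).

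Cytokine genes were higher in 9, lower in 4 and not called in 6 of 19, with Cxcl2 (9.12), Il18 (7.26) and Il1a (6.82) higher and Il33 (−8.67) and Il6 (at least 64.4-fold) lower. Stress genes were higher in 9 and lower in 4 of 21, with the heme oxygenase gene Hmox1 (5.05) higher and Hspb1 (at least 831-fold) lower. Proteases gave 5 higher and 8 lower of 21, with Mmp12 (7.36) higher and Adamts4 (at least 519-fold) and Adamts1 (at least 356-fold) lower. Growth factors gave 2 higher and 9 lower of 22, with Igf1 (6.54) higher and Ptn (at least 797-fold) lower. MAPK response genes gave 5 higher and 10 lower of 24 with Phlda1 (−9.20) and Spry1 (at least 76.4-fold) lower, stem genes 3 higher and 8 lower of 15 with Nes (−6.71) and Sox2 (−3.86) lower, and interferon genes 5 higher and 2 lower of 17 with Ifi44 (3.13) higher. Cell cycle genes gave 2 higher and 3 lower of 23, with Mki67 (2.18) higher and Rrm2 (−6.03) lower, and smooth muscle genes 0 higher and 4 lower of 12. Adjusted over the list alone, more members were lower among stress (6), cytokine (5), MAPK (11), stem (9) and interferon genes (3), and 3 growth factor genes were higher.

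These 8 pathway lists and the smooth muscle list were not called in TRKA versus p75 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.145 cytokines, 0.0623 stress, 0.0915 proteases, 0.0973 growth factors, 0.226 MAPK and smooth muscle, 0.156 stem, 0.462 interferon, 0.494 cell cycle). Of these, protease, growth factor, stress and stem genes were called in some alternatives, proteases lower with quantile normalization (adjusted p = 0.00647) and in the authors' values (0.00641). Interferon genes had a median of 0.57 and a mean of −0.11. In all, limma with Benjamini-Hochberg adjustment called 3872 genes higher and 3479 lower, 35.7% of those tested. Of the called genes 52.7% were higher, and 66.6% with normexp background correction. Among features without a gene symbol 73.9% of calls were higher in TRKA, with a median of 0.49, against 42.1% and −0.35 with a symbol. Camera set the lists, whose members have symbols, against all features tested, so this split can push lists toward lower in TRKA. Between these groups the median of all genes was −0.01, 0.24 with quantile normalization and 0.37 with normexp, so differences of that size depend on scaling.

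TRKA cells set against CD90 cells, on the other slide, had 21 of 22 macrophage genes higher and 20 of 23 fibroblast genes lower. The chemokine gene Ccl6 (287910, chromosome 10, 71660623 to 71660682) was higher in TRKA by 13.30, Cd163 by 12.13, Snx20 by 11.86 and the complement gene Cfd by 10.43. Trem1 (9.99), Sh3tc1 (9.84), Ccl12 (9.49), Exoc6 (9.26), Tbxas1 (9.20) and Lgals9 (at least 436-fold) were higher as well. The largest adjusted p was 0.000155 (limma, Benjamini-Hochberg). Of these, Cd163, Snx20, Trem1, Sh3tc1, Exoc6 and Tbxas1 were measured on 1 CD90 array, Ccl6 on 2 and Lgals9 on 0.

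Ptprd, a receptor phosphatase of cell adhesion (313278, chromosome 5, 94280293 to 94280352), stood at 4.66 ± 0.13 in CD90 and was lower in TRKA by −12.27, with 1 TRKA array above background. The mesenchymal growth factor Fgf7 was at least 3223-fold lower, Nid1 at least 2382-fold, the carbonic anhydrase Car3 at least 2325-fold, Sema3d at least 1529.9-fold, Nedd4 at least 1523-fold, Lum at least 1358-fold, Col6a1 at least 1256-fold and the actin regulator Enah at least 1047-fold. Lox, which cross-links collagen, fell by 10.89 and was measured on some TRKA arrays only. All 10 had an adjusted p of at most 0.000179 in limma with Benjamini-Hochberg adjustment.

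Macrophage genes were higher in TRKA in 21 of 22 with 1 not called (median 5.10), among them Cd53 (8.79), C1qa (6.89) and Lcp1 (6.80). Fibroblast genes were lower in 20 of 23 with 3 not called (median −6.35), with Postn (−10.61) and Loxl1 (at least 729-fold), and smooth muscle genes in 10 of 12 with 2 not called (median −4.62), with Mylk (−9.03), Lmod1 (at least 66.8-fold) and Rgs5 (at least 41.2-fold). Counts adjusted over the list alone were the same but for 1 macrophage gene lower. Camera with Benjamini-Hochberg adjustment called the 3 lists (adjusted p = 8.73e-14, 2.73e-09 and 3.00e-06), also with an estimated correlation (0.000481, 0.00377 and 0.00134).

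Axon guidance genes were lower in 18 and higher in 1 of 26 with 7 not called (19 lower adjusted over the list alone; median −4.79), including Ncam1 (at least 429-fold), Robo1 (at least 253-fold) and Slit2 (−8.03). Fatty acid and cholesterol genes were lower in 9 of 19 with 10 not called (12 lower adjusted over the list alone; median −2.88), with Fads2 (−6.08). Stress genes were higher in 12 and lower in 1 (Hspb1) of 21 with 8 not called, the same counts adjusted over the list alone and a median of 1.75, with Atf3 (4.27) and Hmox1 (4.00) higher. Camera with Benjamini-Hochberg adjustment gave adjusted p = 1.38e-08, 0.00079 and 0.000119 for the 3 lists. With an estimated correlation these were 0.000481, 0.00713 and adjusted p = 0.0578, which loses the stress call.

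Cytokine genes were split between TRKA and CD90, 7 higher and 7 lower of 19, with Il1a (at least 314-fold) and Cxcl2 (8.15) higher and Cxcl12 (−8.11) and Il33 (−5.89) lower. Proteases gave 5 higher and 6 lower of 21, with Plat (at least 420.0-fold), Adamts1 (at least 199.8-fold) and Mmp2 (−7.25) lower, and growth factors 2 higher and 5 lower of 22, with Ptn (at least 201-fold) lower. Cell cycle genes gave 2 higher and 4 lower of 23 with Rrm2 (−7.42) and Top2a (−5.78) lower, MAPK response genes 5 higher and 8 lower of 24 with Epha2 (−7.08) lower, stem genes 1 higher and 5 lower of 15 with Klf4 (−5.72) lower, and interferon genes 4 higher and 1 lower of 17 with Ifi44 (3.09) and Psmb9 (2.87) higher. Glia genes gave 2 higher and 3 lower of 23 with Ncam1 and S100b (at least 28.1-fold) lower, and myelin genes 1 higher and 1 lower of 13 with Mog (at least 137-fold) lower. With adjustment over the list alone, 8 cytokine genes were higher, 9 MAPK and 6 stem genes lower and 3 interferon genes higher, with the other counts unchanged. None of these 9 lists was called by camera with Benjamini-Hochberg adjustment (adjusted p = 0.326 cytokines, 0.153 proteases and growth factors, 0.0657 cell cycle, 0.325 MAPK and stem, 0.409 interferon, 0.414 glia, 0.654 myelin). Protease, cell cycle and growth factor genes were called lower in some alternatives, proteases with quantile normalization at adjusted p = 0.00539 and cell cycle with normexp at 0.00729.

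In TRKA versus CD90, limma with Benjamini-Hochberg adjustment called 3754 genes higher and 3419 lower, 34.9% of those tested. The share higher was 52.3%, and 62.3% with normexp. The median of all genes was −0.09, 0.22 with quantile normalization and 0.23 with normexp. Features without a symbol were again higher in TRKA (72.2% of calls, median 0.39) and those with a symbol lower (42.5%, median −0.41). This can again push lists toward lower in camera. Slide and scan cannot be told apart from the groups here.

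**Figure D3:**
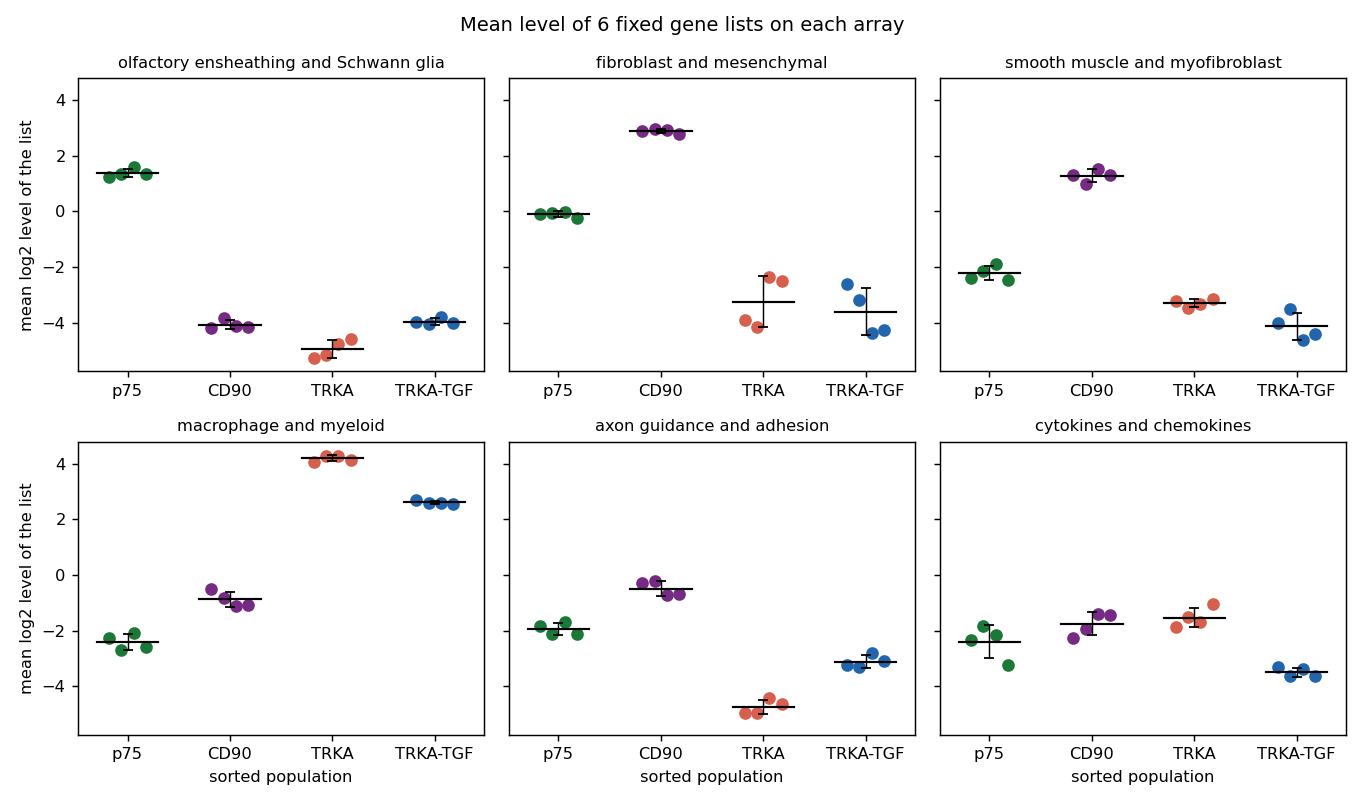
Mean log2 level relative to the 75th percentile of the array over the members of 6 gene lists on each array (points) by population. Macrophage genes were high in TRKA and TRKA-TGF, with a median of 6.66 in TRKA versus p75, glia genes in p75 (−7.02 in TRKA versus p75) and fibroblast genes in CD90 (−6.35 in TRKA versus CD90).

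TRKA-TGF cells, compared with TRKA cells, had 2776 genes higher and 2658 lower, with 9 of 19 cytokine and chemokine genes lower and 2 higher. The Ras regulator Rasa1 (25676, chromosome 2, 14209523 to 14211342) was at least 915-fold higher, the chemokine gene Cxcl13 at least 521-fold, the synaptic scaffold gene Homer3 at least 453-fold, Pxdc1 at least 394-fold, the polyamine regulator Azin1 at least 388-fold, Snx10 at least 305-fold and C1h9orf85 at least 273-fold. Cd9 (9.23), Tvp23b (9.02) and Dnm1 (8.91) were higher as well and were measured on 2, 2 and 1 TRKA arrays. The largest adjusted p was 0.000352 (limma, Benjamini-Hochberg).

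Cd163 stood at 5.11 ± 0.34 in TRKA and was at least 4623-fold lower in TRKA-TGF. Arg1 was at least 398-fold lower, and Thbs1 (−9.93), Gda (−8.72), the chemokine genes Ccl12 (−8.57) and Cxcl1 (−7.80), the interleukin gene Il1a (−8.57), Ltbp2 (−8.10), the protease inhibitor Slpi (−8.03) and haptoglobin, Hp (−7.98), were lower. Ccl12, Slpi and Hp were measured on all 8 arrays, and Thbs1, Gda, Cxcl1, Il1a and Ltbp2 on some TRKA-TGF arrays only. The largest adjusted p, that of Gda, was 0.00913 (limma, Benjamini-Hochberg). Ngfr was at least 81.9-fold higher in TRKA-TGF (adjusted p = 0.000474; exact permutation p = 0.0286, the smallest possible with 4 and 4 arrays). Over the 1491 genes called in CD90 versus p75, TRKA-TGF differed from TRKA in the p75 direction by a mean of 0.0819 (exact permutation p = 0.0571). Of these genes 51.5% differed in that direction. Over genes well above background on all 16 arrays the shift went the other way (−0.0465, 46.9%).

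**Figure D4:**
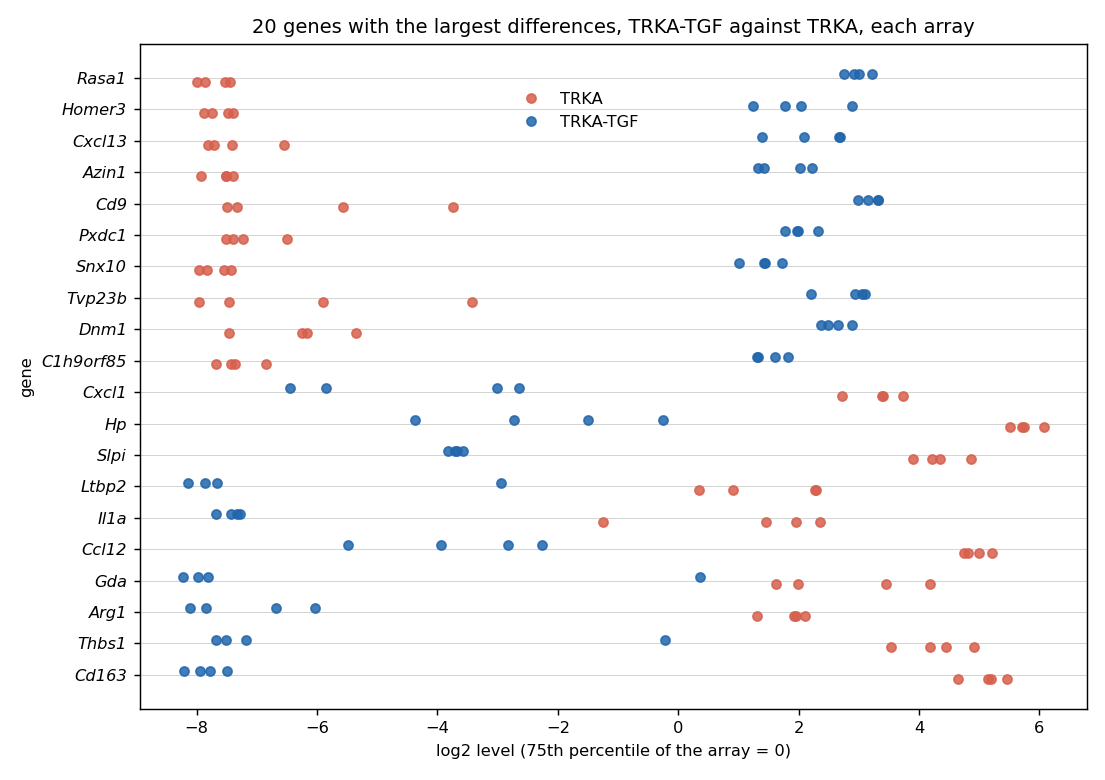
Log2 level relative to the 75th percentile of the array in TRKA and TRKA-TGF for the 10 genes higher and the 10 lower in TRKA-TGF that the naming rule takes; each point is 1 array. Cd163 was at least 4623-fold lower and Rasa1 at least 915-fold higher.

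Cytokine and chemokine genes were lower in 9 and higher in 2 of 19 with 8 not called (10 lower adjusted over the list alone; median −2.54), with Cxcl2 (−7.67), Il1b (−5.41) and Ccl2 (−4.48) lower. Stress and immediate early genes were lower in 9 of 21 with 12 not called, the same adjusted over the list alone, and a median of −1.07. Ier2 (−5.64), Egr1 (−5.09, adjusted p = 1.18e-09 in limma with Benjamini-Hochberg adjustment), Btg2 (−5.06) and Zfp36 (−3.15) were among them. Macrophage genes were lower in 7 of 22 with 15 not called (1 higher and 7 lower adjusted over the list alone; median −1.15), with C1qb (−3.86) and Cd74 (−3.66). Axon guidance genes were higher in 6 of 26 with 20 not called, the same adjusted over the list alone, and a median of 1.04, with Slit2 (8.42), Nrp1 (6.11), Sema3c (6.11) and Sema3b (5.61).

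Camera with Benjamini-Hochberg adjustment called these 4 lists, cytokines (adjusted p = 0.0018), stress (0.000263), macrophage (0.0018) and axon guidance (0.0208). With an estimated correlation the cytokine call held (0.0377) and the other 3 were lost (adjusted p = 0.0694 each). With quantile normalization those 3 were lost as well (adjusted p = 0.149 for stress, 0.483 for macrophage and 0.312 for axon guidance genes).

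MAPK response genes, downstream of the EGF receptor that TGF-α binds, were higher in 3 and lower in 4 of 24, with Spry1 (at least 6.97-fold) higher and Ier3 (−3.94) and Myc (−2.80) lower. Interferon genes gave 2 higher, Ifit2 (at least 63.0-fold) and Ifit3 (at least 16.7-fold), and 3 lower of 17, with Psmb9 (−2.53). Proteases gave 5 higher and 4 lower of 21, with Plat (at least 58.7-fold) and Adamts4 (at least 41.7-fold) higher, and growth factors 3 higher and 2 lower of 22, with Hgf (at least 49.4-fold) higher and Nrg1 (−5.04) lower. Cell cycle genes gave 1 higher and 5 lower of 23, with Birc5 (−3.84) and Mki67 (−3.67) lower, fatty acid and cholesterol genes 3 higher and 2 lower of 19, with Srebf1 (5.47) higher and Hmgcs1 (−2.60) lower, and stem genes 2 higher and 1 lower of 15, with Klf4 (6.53) higher. Glia genes gave 3 higher and 1 lower of 23, with S100b (at least 56.3-fold) higher, myelin genes 3 higher of 13, with Cnp (4.34), fibroblast genes 2 higher and 4 lower of 23, with Loxl1 (at least 9.43-fold) higher and Col1a1 (−4.26) lower, and smooth muscle genes 3 lower of 12, with Tpm2 (−5.79). Counts adjusted over the list alone were lower or higher by 1 or 2 genes in 4 lists, in which 3 interferon, 2 growth factor and 2 cell cycle genes were higher and 1 smooth muscle gene lower.

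None of these 11 lists was called in TRKA-TGF versus TRKA by camera with Benjamini-Hochberg adjustment (adjusted p = 0.0538 cell cycle, 0.464 fibroblast, 0.514 glia and smooth muscle, 0.882 the other 7). Cell cycle genes were called lower in some alternatives, at adjusted p = 0.00768 without TRKA replicate 3. For MAPK genes the median was 0.20 while the test pointed down. In all, limma with Benjamini-Hochberg adjustment called 2776 genes higher and 2658 lower, 26.4% of those tested. The share higher was 51.1%, but 39.9% with quantile normalization, 39.1% with normexp and 39.9% in the authors' values. The median of all genes was 0.19 and moved to −0.13 with quantile normalization and −0.16 with normexp. Features with a symbol were higher in TRKA-TGF in 62.3% of calls (median 0.44) and those without in 31.8% (median −0.20). In camera this split can push lists toward higher in TRKA-TGF, the called axon guidance list among them. In simulated arrays with each group's own spread and few changed genes, 174 of 297 calls of this comparison fell on unchanged genes, so its calls are less certain. The simulation held far fewer changed genes than were called here, so that share is not an estimate for the real calls. TRKA versus p75 and TRKA versus CD90, which hold the same TRKA arrays, were not simulated. The groups shared no slide, so slide, scan and conditioning cannot be told apart.

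TRKA-TGF cells had 1639 genes higher and 1470 lower than p75 cells. Fabp4 (79451, chromosome 2, 93536175 to 93538589), at 5.79 ± 0.03 in TRKA-TGF, was at least 9954-fold higher, the macrophage metal transporter Slc11a1 at least 2034-fold and Klra5 by 11.32. Klra5 was measured on some p75 arrays only. Pramel36 was at least 6932-fold lower, Scn7a at least 4518-fold and Egflam at least 2094-fold. The largest adjusted p was 0.000292 for the higher and 8.11e-05 for the lower genes (limma, Benjamini-Hochberg). Slide and group cannot be told apart in this comparison.

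Macrophage genes were higher in TRKA-TGF than in p75 in 19 of 22 (20 adjusted over the list alone; median 4.84), glia genes lower in 19 and higher in 1 of 23 (median −5.38), myelin genes lower in 5 of 13 (median −2.12), fibroblast genes in 10 of 23 (median −3.33) and smooth muscle genes in 5 of 12 (median −0.85). Lower medians were also seen for cell cycle (6 lower of 23, median −1.50), fatty acid and cholesterol (7 lower and 1 higher of 19, median −2.50), MAPK response (9 lower and 1 higher of 24, median −1.74), protease (11 lower and 4 higher of 21, median −2.02), growth factor (8 lower and 3 higher of 22, median −1.48), axon guidance (10 lower and 1 higher of 26, median −0.64) and stress genes (8 lower and 1 higher of 21, median −0.52). These 12 lists were called by camera with Benjamini-Hochberg adjustment, with adjusted p = 6.71e-21 for macrophage and for glia genes, 2.11e-09 for fibroblast, 1.53e-05 for fatty acid, 1.77e-05 for myelin, 0.000114 for MAPK, 0.000331 for cell cycle, 0.000731 for protease, 0.00172 for axon guidance, 0.0083 for smooth muscle and 0.0164 for growth factor and stress genes. The stress call was lost with an estimated correlation (adjusted p = 0.161) and the growth factor call with the stricter filter (0.0569). Cytokine (3 higher, 5 lower of 19; adjusted p = 0.161), interferon (2 higher of 17; 0.0892) and stem genes (1 higher, 5 lower of 15; 0.0529) were not called by camera, although stem genes were called lower in some alternatives (0.0309 without a filter). Adjusted over the list alone, more members were lower among fatty acid (11), growth factor (11), MAPK (10), cell cycle (9), stress (9), stem (7), myelin (6) and fibroblast genes (11).

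TRKA-TGF and CD90 cells were compared on the same slide, with 1589 genes higher and 1480 lower in TRKA-TGF. The myeloid receptor genes Trem1 (11.08) and Lilra5 (10.08) and the sterol receptor gene Nr1h3 (at least 882-fold) were higher, and Ptprd (at least 3409-fold), the tenascin gene Tnn (at least 2729-fold) and Car3 (at least 2674-fold) were lower. Trem1 and Lilra5 were measured on some CD90 arrays only. The largest adjusted p was 0.00212 for the higher and 0.000702 for the lower genes (limma, Benjamini-Hochberg).

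Macrophage genes were higher in TRKA-TGF than in CD90 in 18 of 22 and lower in 1 (median 3.49), whereas fibroblast genes were lower in 19 of 23 (22 adjusted over the list alone; median −6.29) and smooth muscle genes in 10 of 12 (median −6.36). Cell cycle genes were lower in 10 of 23 (median −3.06), axon guidance genes in 12 of 26 with 1 higher (median −2.39), fatty acid and cholesterol genes in 5 of 19 (10 adjusted over the list alone; median −1.93), MAPK response genes in 8 of 24 (median −1.28) and protease genes in 9 of 21 with 3 higher (median −0.81). Camera with Benjamini-Hochberg adjustment called them (macrophage, adjusted p = 2.70e-14; fibroblast, 6.20e-21; smooth muscle, 2.05e-12; cell cycle, 8.42e-08; axon guidance, 8.77e-07; fatty acid, 1.42e-05; MAPK, 0.000307; protease, 0.00812), all also with an estimated correlation. Growth factor (4 lower, 1 higher of 22), cytokine (7 lower, 2 higher of 19) and interferon genes (2 higher of 17, median 0.88) were called at adjusted p = 0.0393 each in camera and lost with an estimated correlation (adjusted p = 0.0630, 0.0612 and 0.268). Glia (4 higher, 3 lower of 23; adjusted p = 0.831), myelin (1 higher, 1 lower of 13; 0.831), stress (5 higher, 2 lower of 21; 0.831) and stem genes (1 higher, 3 lower of 15; 0.234) were not called by camera. With adjustment over the list alone, 20 macrophage genes were higher, and 13 cell cycle, 13 axon guidance, 10 MAPK, 8 cytokine and 7 growth factor genes were lower. Stress genes had a median of −0.07 and a mean of 0.13.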

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

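Among the named genes, 329 sets of 4 replicates were searched for a replicate that stands far from the other 3, and 19 sets (5.78%) held one. Chance puts about 1 in 20 groups there, so this number of sets is near what chance gives. None of 12 sets of array measures (percent above background and the like) held such a replicate. The ratio given is the gap to the nearest replicate over the whole range of the 4.

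In CD90 cells, replicate 1 stood apart for Alcam (1.94, others 2.08 to 2.09, ratio 0.917), Csf1r (1.44, others 0.11 to 0.25, 0.892) and Sema3a (−4.58, others 1.10 to 1.55, 0.927). Without that array Sema3a would stand farther from p75 than the mean used here. Replicate 4 stood apart for Ccl12 (−7.23, others −3.96 to −3.29, 0.8293), Col6a2 (0.55, others 1.33 to 1.47, 0.851) and Spry1 (0.14, others −2.47 to −2.35, 0.955). Replicate 2 did so for Cldn5 (−3.78, others −5.24 to −5.04, 0.861) and replicate 3 for Cnn1 (3.74, others 2.99 to 3.07, 0.883).

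In p75 cells, replicate 1 stood apart for Adamts1 (2.10, others 1.46 to 1.48, 0.969), Tagln (4.10, others 4.48 to 4.56, 0.833) and Uchl1 (−4.18, others −1.41 to −0.88, 0.842), and replicate 4 for Top2a (−1.38, others −3.42 to −3.17, 0.877).

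In TRKA cells, replicate 2 stood apart for Ifi44 (2.77, others 1.504 to 1.70, 0.848), Tgfa (2.28, others −0.61 to −0.38, 0.921) and Zfp36 (−0.88, others −1.34 to −1.27, 0.861), and replicate 3 for Ier2 (3.88, others 3.21 to 3.30, 0.861). The Tgfa mean of TRKA thus rests largely on 1 array.

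In TRKA-TGF cells, replicate 3 stood apart for Gnal (−2.26, others −3.38 to −3.31, 0.938) and Hmgcs1 (0.44, others −0.28 to −0.20, 0.888), and replicate 2 for Pdgfb (−3.99, others −0.30 to 0.19, 0.883). No array was left out of the fit for these values.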

How the results depend on the processing

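The myeloid, glial and fibroblast differences held in nearly every alternative, whereas the number of genes called and the weaker lists moved. Of 3331 values of named genes under other settings, 3174 kept sign and call, 134 lost the call, 17 gained one and 6 changed sign. Leaving out single arrays kept 5200 of 5408, with 197 calls lost and 11 gained. The cause of a change was not tested unless stated.

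With array weights, CD90 versus p75 gave 2237 called genes (1491 in the fit used), TRKA-TGF versus p75 gave 5010 (3109) and TRKA-TGF versus CD90 gave 4676 (3069), while TRKA versus p75 fell to 5718 (7351), TRKA versus CD90 to 5380 (7173) and TRKA-TGF versus TRKA to 3986 (5434). In fits of the 2 groups alone the same 6 gave 1757, 4443, 4183, 5067, 4945 and 3843. Without the TRKA arrays, whose spread is the widest, the 3 gave 2267, 4488 and 4519. Over the 9948 genes well above background on all 16 arrays the 6 comparisons gave 819, 4555, 4378, 3616, 1731 and 1673 called genes. That setting tests fewer genes and removes those low in any group, and the share higher moved to 44.6, 78.6, 79.5, 24.3, 64.6 and 66.0%. In that setting 1 list was called in CD90 versus p75, 6 in TRKA-TGF versus p75 and 7 in TRKA-TGF versus CD90, against 7, 12 and 11. Only 12 of the 20 lists kept enough genes to be tested there. Of the 7 lists of CD90 versus p75 these were 4, of which the fibroblast (adjusted p = 0.239), cell cycle (0.239) and stress lists (0.2505) lost the call and the macrophage list kept it. In TRKA-TGF versus p75 the growth factor (0.0815), cell cycle (0.126) and protease calls (0.210) were lost and 3 called lists could not be tested.

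Leaving out each array gave 1198 to 1670 called genes in CD90 versus p75, 6278 to 7670 in TRKA versus p75, 6287 to 7372 in TRKA versus CD90, 4327 to 5819 in TRKA-TGF versus TRKA, 2531 to 3441 in TRKA-TGF versus p75 and 2441 to 3385 in TRKA-TGF versus CD90. Each of these fits has 1 array fewer. The call of Gda in TRKA-TGF versus TRKA was lost with array weights.

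The fry test, which compares a list with no change instead of with other genes, called 13 lists in CD90 versus p75, 17 in TRKA versus p75, 16 in TRKA versus CD90 and 11 in TRKA-TGF versus TRKA. It put the glia list in TRKA-TGF versus CD90 in the other direction than camera (adjusted p = 0.0389). In TRKA-TGF versus TRKA, 1 list was called with quantile normalization, 1 in the authors' values and 1 with an estimated correlation, against 4. In the authors' values the adjusted p was 0.487 for macrophage, 0.150 for stress and 0.309 for axon guidance genes in camera, and the axon guidance call was lost without TRKA replicate 1 (0.0611). In TRKA-TGF versus p75 the growth factor call was lost with the stricter filter (0.0569). In TRKA-TGF versus CD90 the protease call was lost in a fit of the 2 groups alone (0.0536). The 3 weak calls there were also lost without single arrays, interferon without CD90 replicate 3 (0.108), growth factor without CD90 replicate 2 (0.0615) and cytokine genes without CD90 replicate 3 (0.0654).

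Some lists that camera did not call were called in alternatives besides fry. In TRKA versus CD90 these were lower proteases with quantile normalization (adjusted p = 0.00539), normexp (0.0475), no filter (0.0385) and the authors' values (0.00532). Cell cycle genes were lower with the same 4 (0.0200, 0.00729, 0.0107 and 0.0197) and without TRKA replicate 1 (0.0408) or 4 (0.0479), and growth factors with no filter (0.0374). In TRKA versus p75 proteases were called lower with the same 4 (0.00647, 0.0127, 0.0360 and 0.00641), growth factors lower with no filter (0.0198) and the 2 groups alone (0.0307), stem genes lower with normexp (0.0410), and stress genes higher with the stricter filter (0.0408), trended and robust moderation (0.0372) and without p75 replicate 4 (0.0396). In TRKA-TGF versus TRKA cell cycle genes were called lower with the mean of probes (0.0336), array weights (0.0372), without TRKA replicate 3 (0.00768), p75 replicate 3 (0.0491) or TRKA-TGF replicate 2 (0.0394), and fibroblast genes lower over genes measured on all 16 arrays (0.0257). In TRKA-TGF versus p75 stem genes were called lower with no filter (0.0309), the mean of probes (0.0431) and without each of 5 single arrays (0.0324 to 0.0492).

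Signs changed for few named genes. With the mean of a gene's probes, Tgfa in TRKA versus p75 went to −2.10 and Ovol1 in TRKA versus CD90 to −0.71, since their probes disagree. In TRKA-TGF versus TRKA, Notch1 (−2.15) went to 0.34 with quantile normalization and 1.06 with normexp, and Gnal (0.83) to −0.79 with quantile normalization and −0.79 in the authors' values.

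The shift of TRKA-TGF toward p75 over the genes called in CD90 versus p75 was 0.0819 (exact permutation p = 0.0571), with 51.5% of genes shifted in that direction. It was 0.0990 with quantile normalization, 0.0649 with normexp, 0.0940 without a filter, 0.0748 with the stricter filter, 0.243 in the fit of the 2 groups alone and 0.0996 in the authors' values, each with the smallest exact p possible (0.0286). With the mean of probes the exact p was 0.0857. Over genes measured on all 16 arrays the shift was −0.0465, in the other direction, and leaving out single arrays gave 0.0111 to 0.169. The shift is small in every setting, and its sign changed once genes low in any group were removed.

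With replicate number as a block the comparisons gave 1322, 7158, 6939, 5114, 2919 and 2845 called genes. On pairing by replicate number, 0 of 4 pairs had a correlation of residuals over 0.1 in any comparison. In TRKA-TGF versus TRKA all 4 arrays correlated best with the array of their own number (r = 0.0123 to 0.0427), against 1 of 4 in each other comparison, so a weak pairing there is not excluded. The block fit called cell cycle genes in TRKA-TGF versus TRKA (adjusted p = 0.0456) and stem genes in TRKA-TGF versus p75 (0.0375), as did several fits without a block. A fit with slide as a block was not run. Levels near background are the least certain, and bounds given as at least N-fold depend on the lowest signal that counts as well above background.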

Other observations

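Markers of other cell types of the mucosa were few and mixed. Epithelial genes gave 0 higher and 2 lower of 16 in CD90 versus p75, with Krt19 at least 46.7-fold lower, 1 higher and 2 lower in TRKA versus p75, 2 higher and 1 lower in TRKA versus CD90, with Krt8 at least 87.8-fold lower, and 1 lower in TRKA-TGF versus TRKA, Cdh1, which was at least 33.1-fold lower and measured on 3 TRKA arrays. Genes of olfactory neurons and sustentacular cells gave none called of 9 in CD90 versus p75, 2 lower in TRKA versus p75 with Gng8 (at least 35.3-fold) and Adcy3 (−4.53), 3 lower in TRKA versus CD90 and 1 higher in TRKA-TGF versus TRKA. Neuronal genes gave 2 of 8 lower in CD90 versus p75, Map2 (at least 31.3-fold) and Nefm (−4.85), 3 lower in TRKA versus p75 and none in TRKA versus CD90 or TRKA-TGF versus TRKA.

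Lymphocyte and mast cell genes gave 1 of 12 higher in CD90 versus p75 (Cd4, 4.26), 2 higher, Cd4 (6.97) and Kit (2.30), and 1 lower, Gata2 (−4.32), in TRKA versus p75, 2 higher and 1 lower in TRKA versus CD90 and none in TRKA-TGF versus TRKA. Endothelial genes gave 1 higher (Erg, 4.31) and 1 lower (Cldn5, −3.90) of 10 in CD90 versus p75, 2 higher and 1 lower in TRKA versus p75, 2 higher in TRKA versus CD90 and 1 each way in TRKA-TGF versus TRKA. Against p75, TRKA-TGF gave 2 epithelial genes higher and 2 lower, 2 olfactory and 3 neuronal genes lower, 1 lymphocyte gene each way, and 2 endothelial genes higher and 1 lower. Against CD90 it gave 1 epithelial gene higher, 2 olfactory genes lower, no neuronal gene, 2 lymphocyte genes higher and 1 lower, and 2 endothelial genes higher and 1 lower.

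These counts moved by at most 2 genes either way when adjusted over the list alone. None of these 5 lists was called by camera with Benjamini-Hochberg adjustment in any comparison. In the order epithelial, olfactory, neuronal, lymphocyte and endothelial, the adjusted p was 0.275, 0.599, 0.201, 0.385 and 0.7504 in CD90 versus p75, 0.879, 0.384, 0.238, 0.462 and 0.462 in TRKA versus p75, 0.414, 0.245, 0.739, 0.739 and 0.684 in TRKA versus CD90, and 0.882 for each in TRKA-TGF versus TRKA. It was 0.692, 0.507, 0.117, 0.507 and 0.212 in TRKA-TGF versus p75 and 0.437, 0.234, 0.831, 0.957 and 0.426 in TRKA-TGF versus CD90. Median and mean differed in sign for epithelial genes in TRKA versus p75 (0.14 and −0.59) and TRKA-TGF versus p75 (0.21 and −0.51), for olfactory genes in TRKA-TGF versus p75 (0.45 and −0.65) and versus CD90 (0.16 and −1.15), for endothelial genes in TRKA versus CD90 (−0.02 and 0.96), and for neuronal (−0.01 and 0.27) and lymphocyte genes (−0.04 and 0.34) in TRKA-TGF versus TRKA.

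The 8 arrays of each comparison can be split into 4 and 4 in 35 ways. For called genes, 1 split of 35, the real one, gave as many in each comparison. Every other split puts arrays of both populations into each group, which widens the spread within groups and lowers the count. The counts of the other splits therefore do not show what chance alone would give, and this test cannot exclude chance. Where the populations shared no slide, the real split was also the split by slide. The real count and the highest other were 1491 and 10 in CD90 versus p75, 7351 and 57 in TRKA versus p75, 7173 and 84 in TRKA versus CD90, 5434 and 38 in TRKA-TGF versus TRKA, 3109 and 5 in TRKA-TGF versus p75 and 3069 and 7 in TRKA-TGF versus CD90. For the number of lists called, the real split alone was highest in CD90 versus p75 (7, highest other 6) and TRKA-TGF versus CD90 (11, highest other 10). Other splits came close in both, so these counts are only weak evidence against chance. Chance cannot be excluded in TRKA versus p75 (6, highest other 6, 3 splits), TRKA versus CD90 (6, highest other 8, 9 splits), TRKA-TGF versus TRKA (4, highest other 6, 4 splits) and TRKA-TGF versus p75 (12, highest other 12, 3 splits). A count of lists alone therefore says little about the real groups.

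The tests that follow on the share of cells, on slides, on genes measured on all 16 arrays or in 1 group and on a common share of p75 cells were chosen only after the results were seen. The test of the common share took the place of an earlier one, on the ratio of upper to lower quartile (6.64) and the median, which came out the same way. The test on genes measured on all 16 arrays was first set on the share called alone, which argued against weaker arrays as the whole cause, and was made stricter because that set depends on the TRKA arrays.

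Myeloid genes were higher in TRKA and TRKA-TGF than in p75 and CD90. A minor share of myeloid cells in a mainly glial or fibroblast sort would leave the other cells' genes near their usual level. In TRKA the p75-high genes stood at a median of 3.00% of their p75 level (upper quartile 17.2%). The CD90-high genes stood at a median of 6.39% of their CD90 level (upper quartile 40.3%). These values argue against a minor share of myeloid cells, although signal lost on the TRKA arrays would also lower them. In TRKA-TGF these medians were 6.28% and 8.74%, but the upper quartile of the CD90-high genes was 85.2%, so the same test leaves it open there. Macrophage genes such as Mrc1 were also higher in CD90 than in p75, so the CD90-high genes are not fibroblast genes alone. The fixed lists were looked at after that. In TRKA-TGF the glia list stood at a median of 2.40% of its p75 level (upper quartile 9.13%). The fibroblast list stood at 1.28% of its CD90 level (upper quartile 2.49%). For the genes of these 2 lists this argues against a mainly glial or fibroblast TRKA-TGF sort. The macrophage list was called within both slides (larger adjusted p = 2.70e-14, camera, Benjamini-Hochberg), and its smallest median under quantile and normexp scaling was 3.46, so neither slide nor scaling explains it. An open hypothesis is that the sort took up mostly myeloid cells, which staining of the sorted cells for a leukocyte protein, or a sort with an isotype control, could decide.

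Many genes were called between TRKA-TGF and TRKA. If fewer probes above background on the TRKA arrays were the whole cause, genes measured on all 16 arrays would hardly be called, yet 36.3% of 9948 were, with 24.3% of these calls higher in TRKA-TGF and a median of −0.30, a skew that the scaling of weaker arrays could produce. Scaled again among themselves by loess, 31.4% were called with 48.8% higher (quantile, 33.9% and 43.0%), so the skew was not all of it. The set keeps only genes detected on every TRKA array, however. Genes seen on all 4 TRKA and no TRKA-TGF arrays were 28, against 624 the other way and up to 49 in other splits, so this test alone leaves it open. Over all genes, looked at after that, 2102 called genes were at least 2-fold lower in TRKA-TGF. The share of calls lower was larger with quantile normalization and normexp. Signal lost on the TRKA arrays would make weak genes lower in TRKA. Levels are relative to a percentile of the same array, however, so such a loss could also raise the brighter genes in TRKA. The genes lower in TRKA-TGF therefore do not decide whether lost signal was the whole cause. For the genes higher and for those lower in TRKA-TGF the explanation stays open. The groups shared 0 slides, so slide and scan cannot be told apart from conditioning.

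Some genes high in p75 cells, such as Ngfr and S100b, were higher in TRKA-TGF than in TRKA. If p75 cells mixed into the TRKA-TGF sort were the whole cause, 19 genes high in p75 and not above background in TRKA would stand at one share of their p75 level. With genes not above background at their upper bound, they ranged from at most 0.0221% (Scn7a) to 8.65% (Ngfr) with a median of 0.768%, and 7 lay more than 4-fold from it (4 above, measured on all 4 TRKA-TGF arrays), which argues against one share as the whole cause. The 4-fold limit was not set from the spread of levels this low, which PCR amplification can widen. Fewer probes above background on the TRKA arrays would raise p75-high and CD90-high genes alike in TRKA-TGF, and the means of these genes were 0.46 and 0.28 higher. The shift toward p75 had an exact p = 0.0571, with 0.0286 in several alternatives and the other sign over genes measured on all 16 arrays, so this explanation could hold and stays open.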
